A study of Mus musculus with 6 samples.

How the data were processed

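Single-colour Agilent arrays were analysed from 6 samples of primary mouse microglia, 3 infected with vector and 3 with sh-U90926 virus, all treated with LPS. Groups and replicate numbers were taken from the sample titles, which give U90926 for all 3 knockdown samples. The source names of sh-U90926 replicates 2 and 3 read U90927 and U90928 in its place; since the level of U90926 was not analysed here, the labels were not checked against the target. Per the labels' protocols, total RNA was amplified to Cy3-labelled cRNA before hybridisation, and per the submitters' processing notes the scans were read with Agilent Feature Extraction 10.7.1.1. Per the file headers, each file holds the scanner output of a single array, with the intensity of every spot (background-corrected processed signal, mean signal and median local background) and quality flags, not normalized between arrays. A deposited table of the authors' processed values holds 4806 probes on a log2 scale; how the authors normalized and selected it is not given in the sources used here.

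Each array has 148260 spots, of which 4974 control spots were left out. Spots marked as non-uniform or population outliers were left out (11 to 37 per array). The spots of 1 probe were averaged on the log2 scale; 51738 probes are spotted 2 times, 39410 a single time and 40 probes 10 times. Of 91188 probes, 16 had no value on some array, which left 91172. The main values are log2 of the processed signal minus the array's 75th percentile over all probes. This set was chosen by a rule fixed beforehand, since on average 57.5% of the probes were well above background. A probe was tested if well above background on all 3 arrays of at least 1 group. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05), and differences are sh-U90926 minus vector. Overlaps of probes were searched in Python 3.11.15 and figures drawn with matplotlib 3.10.9. A probe not well above background on any array of a group has only a bound there: the bright group's mean was set against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array.

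The gene name columns of the files repeat the probe identifier, no probe has a description or a coordinate, and no genome sequence was used. The gene table used for U90926 and its neighbours (assembly GRCm38.p6) matched 0 probe identifiers. Every probe was therefore its own feature, and the level of U90926, the level of Cxcl2, the tests of 36 gene lists with 690 genes and the cell type markers were not analysed here. The rule for named genes, fixed before the data were examined, takes U90926 and Cxcl2, the 10 genes with a symbol that rose most and the 10 that fell most, the leading members of each list, and up to 3 unnamed probes per direction with the largest change. Only the last part could be applied, to probes past the threshold whose groups do not overlap, and the first 2 probes per direction are named. For checks across settings, 3 unnamed probes per direction and 7 more per direction that were well above background on all arrays were followed, the latter chosen after their values were seen.

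Precision was limited by the number of arrays. The median SD between arrays of a group was 0.425 log2 units, while duplicate spots of 1 array had a median SD of 0.0823 to 0.124. No pair of arrays held the same values (highest correlation 0.972). Leading principal components took 53.1%, 23.9% and 15.5% of the variance, and the first separated the groups. Replicate 1 of both groups was scanned in run 1 and replicates 2 and 3 in run 2. Slide 2 held vector replicate 2 and sh-U90926 replicates 2 and 3, and the other arrays were on slides of their own. Whether the replicate numbers pair the samples was decided from the correlation of the arrays' deviations from their group means, which was 0.654, 0.708 and 0.538 for the 3 same-numbered pairs. All lie over the limit of 0.1, so the numbers were taken as pairs on this evidence from the data; the labels do not state a pairing, and the fit without pairs stays the main result.

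The columns of the deposited log2 table were set against quantile-normalized log2 signals of the scanner files. Each column correlated at 1.00 with a single array, of its own group but of another number: table columns vector 1, 2 and 3 matched arrays vector 2, 3 and 1, and columns sh-U90926 1, 2 and 3 matched arrays sh-U90926 2, 3 and 1. The columns are thus uncentred log2 values with medians of 7.01, 7.14, 7.07, 6.87, 7.14 and 6.80, the groups and the pairs are unaffected, and which of the sources carries the intended numbers stays unknown. The replicate numbers used here are those of the scanner files.

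Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, the percentile over probes detected on all arrays, other filters on dim probes, the replicate number and the slide as blocks, eBayes with trend and robust, array weights, each array left out, the authors' deposited table and other thresholds. The scan run as a block, run 2 alone, removal of each array's loess trend with GC content, the slide as a random block, combinations with the replicate block, pairs left out and the paired test of the control genes were chosen after seeing the data. The fit was tested on simulated data with the real probe means, pair effects and spread of 45749 probes and 200 probes changed. Without the pairs 0% of the probes changed by 1 or by 2 log2 units and 25.8% of those changed by 3 were recovered for sh-U90926 against vector, with 0 false calls. With the pairs these shares were 0%, 14.9% and 47.0%, with 1 false call. In the simulation 200 probes changed, so the adjusted threshold was stricter than in the real comparison.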

Results

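Primary mouse microglia, the resident macrophages of the brain, were infected with a virus carrying either an empty vector or a short hairpin RNA against U90926 (sh-U90926) at a multiplicity of infection of 50. After 48 h the cells were given lipopolysaccharide (LPS), a bacterial cell wall component that activates microglia through toll-like receptor 4, at 100 ng/ml for 3 h. U90926 is a long non-coding RNA. In the gene table used here (assembly GRCm38.p6) it lies between the protein-coding genes Uso1 and Ppef2. Total RNA from 3 samples of each group was labelled with Cy3 and hybridised to 6 single-colour arrays, each with 91188 different probes of 60 bases. The comparison of the groups asks how the RNA content of LPS-treated microglia differs when U90926 is targeted. Every sample had received LPS, so the LPS response itself was not measured against untreated cells.

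Probes well above background made up 67.1%, 53.7% and 45.5% of the array in vector replicates 1, 2 and 3, and 67.3%, 62.7% and 49.0% in sh-U90926 replicates 1, 2 and 3. No spot was saturated. The probes that were well above background on all 3 arrays of at least 1 group numbered 45749, and these were tested. The files do not pair the probes with gene names, so the level of U90926 itself, of Cxcl2 and of the 36 gene lists chosen before the data were examined was not analysed here, and the changes below are those of probes and of groups of probes. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

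Targeting U90926 was accompanied by steep losses of signal from probes that were bright in vector microglia. In total 1738 probes were lower and 1370 were higher in the sh-U90926 arrays (limma, Benjamini-Hochberg adjusted p under 0.05), together 6.79% of those tested, and 9246 probes had an unadjusted p under 0.05. The falls were larger than the rises. The median fall was 4.91-fold and the median rise 3.69-fold, or 4.84-fold and 3.55-fold when probes not well above background on any array of the dimmer group were set to their bounds. Falls of at least 8-fold numbered 539 (31.0% of the falls) against 150 rises of that size (10.9% of the rises). After normexp background correction, whose offset of 50 compresses dim signals, 261 falls reached 8-fold, while 514 of the 539 were still lower with an adjusted p under 0.05. Among the probes well above background on all 6 arrays, 320 fell and 25 rose by at least 8-fold, and 54 fell by at least 32-fold while none rose by that much; the largest fall measured in this way was 735-fold and the largest rise 24.0-fold.

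The 539 steep falls had a median signal of 1360 in the vector arrays and 69.2 in the sh-U90926 arrays, whereas the 150 steep rises had a median of 14.2 in the vector arrays and 208 in the sh-U90926 arrays. Probes well above background only in the vector arrays were fewer than those only in the sh-U90926 arrays but had the higher bounds. On average the share of probes well above background was 4.22 percentage points higher in the sh-U90926 arrays, which bears on these counts. Of 159 probes well above background on all 3 vector arrays and on no sh-U90926 array, 140 were lower with an adjusted p under 0.05, 80 of them by at least 8-fold, and the largest by at least 1580-fold. Of 461 probes with the opposite pattern, 206 were higher, 32 of them by at least 8-fold, and the largest by at least 32.1-fold. With the replicate number as a block, 156 of the 159 were lower and 369 of the 461 higher. Both sets were picked by their detection on these same arrays, so the direction of their changes was largely given by the choice. When the tested probes were divided into 10 equal bins by their mean level over all 6 arrays, the brightest bin held 184 falls and 6 rises and the dimmest 190 falls and 406 rises. Part of this went with a trend over all probes: the median log2 difference (sh-U90926 minus vector) was -0.32 in the brightest bin and 0.44 in the dimmest. Quantile normalization, which moved these medians to 0.08 and 0.27, left 169 falls and 21 rises in the brightest bin.

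**Figure D1:**
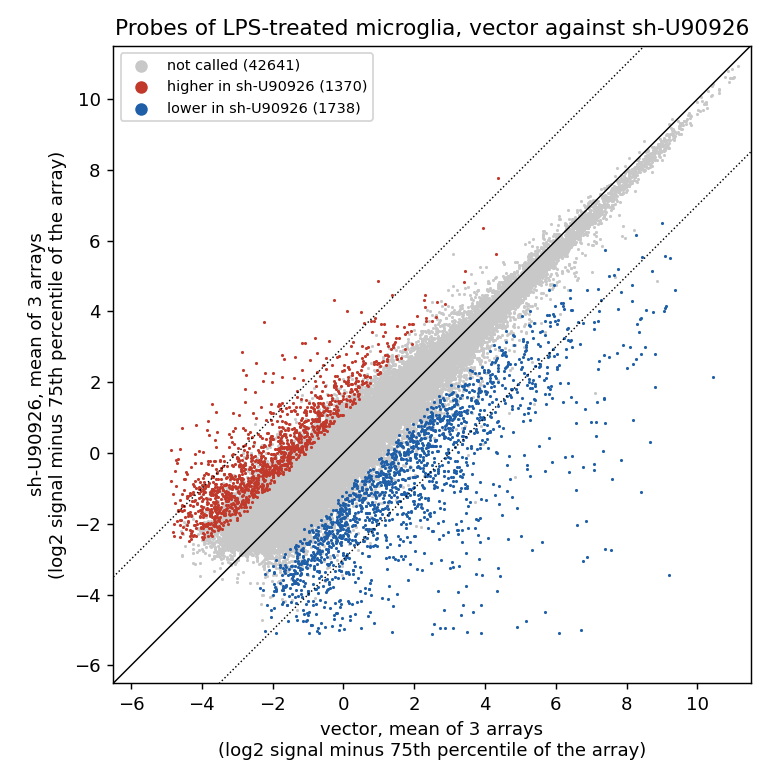
Each point is a tested probe, with its mean over 3 vector arrays on the x axis and over 3 sh-U90926 arrays on the y axis, both as log2 signal minus the array's 75th percentile; the solid line marks equal levels and the dotted lines an 8-fold difference. The 1738 probes that were lower reach farther from the line than the 1370 that were higher, mostly among probes that were bright in the vector arrays.

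**Figure D2:**
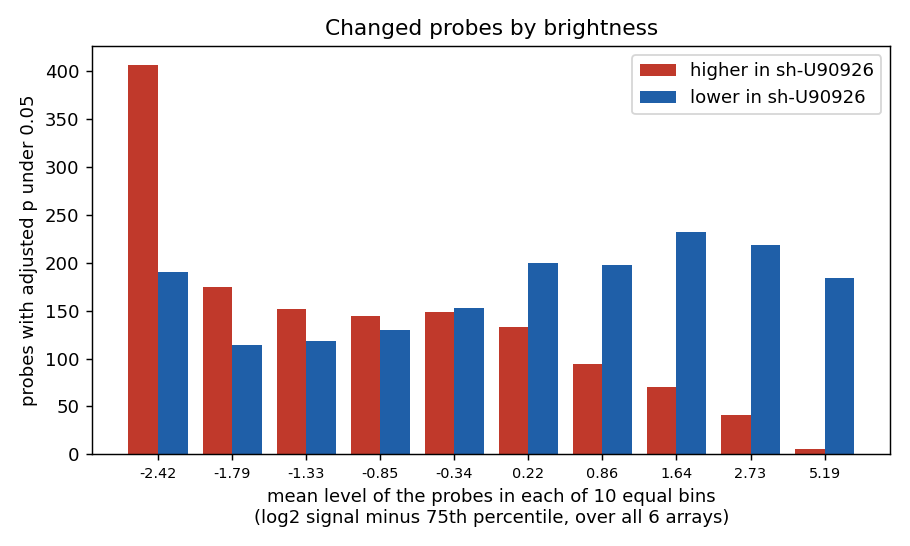
Bars give the number of probes higher and lower in the sh-U90926 arrays (adjusted p under 0.05) in each of 10 equal bins of the tested probes, ordered by mean level over all 6 arrays on the x axis (log2 signal minus the array's 75th percentile). The brightest bin holds 184 falls and 6 rises, the dimmest 190 falls and 406 rises.

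The probe A_55_P2016462, first by fitted fall, stood at 9.20 ± 0.81 (log2 signal above the array's 75th percentile, mean ± SD, n = 3) in vector microglia and at -3.43 ± 3.35 in sh-U90926 microglia, where only 1 of 3 arrays had it well above background. Its fitted log2 difference of -12.63 ± 1.42 (SE, limma adjusted p = 0.00307) is set in part by background values on the other 2 of these arrays and is no exact size. With the slide as a block it was -10.51 (limma adjusted p = 0.103) and in scan run 2 alone -11.31 (limma adjusted p = 0.0975), past the threshold in neither. It was lower on every sh-U90926 array than on any vector array, which held for all 1738 falls and was a condition of its choice. The next, A_55_P1997756, fell from 6.70 ± 0.29 to -5.00 ± 0.93 (SD, n = 3), was not well above background on any sh-U90926 array, and was lower by at least 1576-fold (limma adjusted p = 0.000166). The largest fitted rise was that of A_65_P13459, from -2.25 ± 0.55 to 3.70 ± 0.58 (SD, n = 3), a log2 difference of 5.94 ± 0.40 (SE, limma adjusted p = 0.000604). A_51_P185906 rose from -2.86 ± 1.08 to 2.86 ± 0.38 (SD, n = 3), a log2 difference of 5.72 ± 0.52 (SE, limma adjusted p = 0.00144). The vector arrays had these rising probes well above background on 2 and 1 of 3 arrays, so their sizes too rest partly on background values. After normexp correction the log2 differences of A_55_P2016462, A_55_P1997756, A_65_P13459 and A_51_P185906 were -9.81, -7.91, 4.33 and 3.62. In scan run 2 alone, with 2 arrays against 2, the rises of A_65_P13459 and A_51_P185906 were 5.88 and 6.28, about as large as over all arrays, and missed the threshold (limma adjusted p = 0.0628 and 0.0615).

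The array carries spots for 2 named genes of glycolysis among its controls, GAPDH and PGK1, each measured near the 3' and the 5' end of its transcript. The levels of the groups overlapped for both genes. The GAPDH 5' probe stood at 9.04 ± 0.70 in vector and 8.84 ± 0.95 in sh-U90926 microglia (log2, SD, n = 3, exact permutation p = 0.7, 2-sided), and the 3' probe at 7.38 ± 0.81 and 7.28 ± 1.16 (exact permutation p = 0.9). The PGK1 3' probe stood at 6.40 ± 0.70 and 5.86 ± 1.32 (SD, n = 3, exact permutation p = 0.7), and the 5' probe at 4.11 ± 0.75 and 3.46 ± 1.37 (exact permutation p = 0.4). With 3 arrays against 3 this test cannot give a p below 0.1, so these values do not show that the genes were unchanged. The difference between the PGK1 5' and 3' probes, which RNA degradation would widen, was -2.29 ± 0.40 in vector and -2.41 ± 0.32 in sh-U90926 microglia (SD, n = 3, exact permutation p = 0.5). Within the same-numbered pairs it was lower in sh-U90926 in 3 of 3, by -0.02, -0.18 and -0.15 log2 units (exact sign-flip p = 0.25, the smallest that 3 pairs allow). The 5' probes of GAPDH (-0.12, -0.50 and -0.001) and PGK1 (-0.63, -1.32 and -0.02) were also lower in 3 of 3 pairs (exact sign-flip p = 0.25 for each, n = 3), but in 1 and 2 of 3 with the percentile taken over probes detected on all arrays. For the GAPDH 3' probe the pair differences were -0.015, -0.485 and 0.219. In 3 of 3 pairs the GAPDH 5' probe thus lay lower against its 3' probe, as for PGK1, which was not tested.

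**Figure D3:**
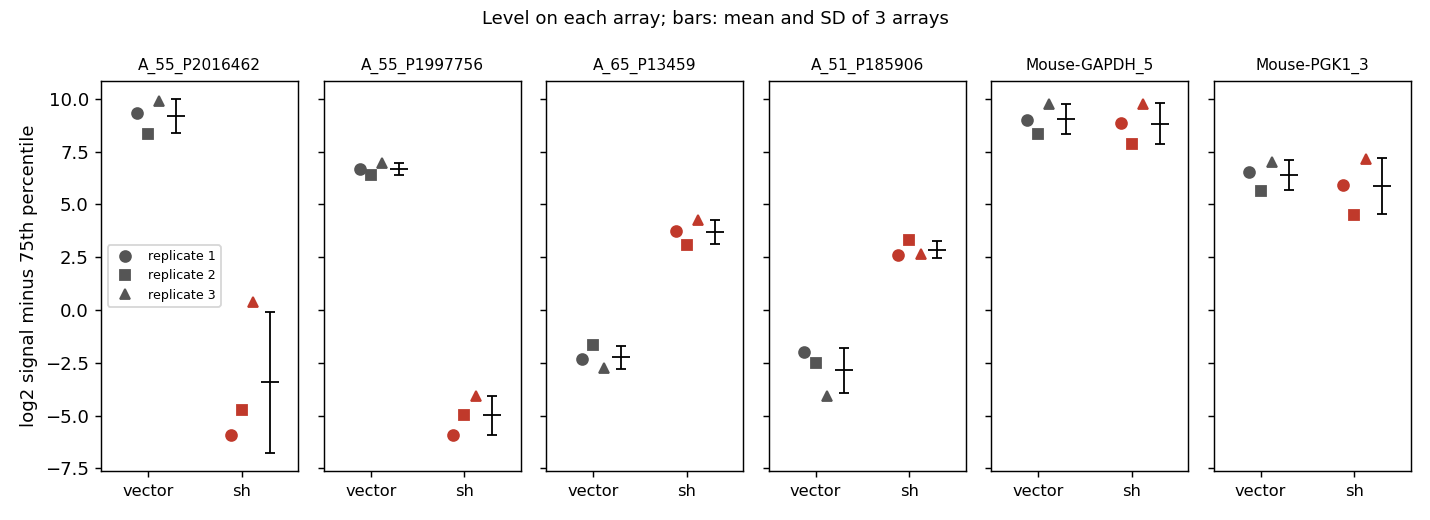
Points give the level of 4 probes and of 2 control genes on each array (y axis, log2 signal minus the array's 75th percentile), with circles, squares and triangles for replicates 1, 2 and 3, and bars for the mean and SD of 3 arrays. The groups are apart for the 4 probes, which were chosen among probes whose groups do not overlap. They overlap for GAPDH and PGK1, which were not chosen in this way. For these 2 genes replicate 2 is the lowest and replicate 3 the highest array of both groups.

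The tested probes fall into 7 series by the start of their identifier, all of which held probes that changed. Series mmu (15885 tested) had 539 rises and 657 falls, series A_55 (13780 tested) 335 and 511, and series A_30 (7677 tested) 96 and 221. Series A_51 (4311 tested) had 215 rises and 176 falls, and series A_52 (2906 tested) 153 and 130. Falls outnumbered rises in series A_30 under every scaling tried without the pairs (194 against 138 with the percentile taken over probes detected on all arrays), but with the replicate number as a block A_30 had 594 rises and 521 falls. In series A_51 and A_52 rises outnumbered falls except after normexp background correction, which gave 139 rises and 172 falls in A_51 and 100 and 120 in A_52, and in series mmu and A_55 falls outnumbered rises except with the percentile over probes detected on all arrays (663 rises and 537 falls in mmu, 519 and 444 in A_55) and with the replicate block (1999 and 1483 in mmu, 1441 and 1230 in A_55). Steep falls were spread over the series, with 171 in A_55, 164 in mmu, 76 in A_51, 66 in A_30, 44 in A_52, 15 in A_66 and 3 in A_65.

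Different probes for the same stretch of RNA changed alike. Among 3144 tested pairs that share at least 30 bases on the same strand, the log2 differences correlated across pairs at r = 0.912 (Spearman's rho 0.836), and all 109 pairs with both probes past the threshold changed in the same direction. Of 50 tested probes that overlap a steeply falling probe, 48 were themselves lower with an adjusted p under 0.05; 43 of the 50 belong to the steep falls, and 491 of the 539 steep falls have no overlapping tested probe. These correlations are across probes, which are not independent replicates.

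Same-numbered arrays of both groups deviated from their group means together, and with the replicate number as a block limma called 5547 probes higher and 4045 lower, among them all 3108 probes called without it. These blocked counts depend on the pairs: without pair 1, 971 probes were higher and 1421 lower, 1995 of the 3108 among them, while 4833 and 3640 were called without pair 2 and 2356 and 2507 without pair 3. The split between rises and falls depended on the scaling: 44.1% of the calls were rises, and 55.9% (1900 higher, 1499 lower) with the percentile taken over probes detected on all arrays, which raised the median log2 difference of all tested probes by 0.21. Single arrays moved the counts by over 1.5 times. There were 479 rises and 817 falls without vector replicate 1, 461 and 718 without vector replicate 3, 586 and 953 without sh-U90926 replicate 1, 2486 rises without vector replicate 2, 868 without sh-U90926 replicate 2 and 558 without sh-U90926 replicate 3. Of the 539 steep falls, between 404 (without vector replicate 3) and 535 (without vector replicate 2) still passed the threshold. The arrays were scanned in 2 runs, each with arrays of both groups. With the run as a block 1408 probes were higher and 1610 lower, in run 2 alone (2 arrays against 2) 11 were higher and 49 lower, and run 1 holds 1 array of each group. The log2 differences of the runs correlated across the 45749 probes at r = 0.859. With the slide as a block, where only slide 2 holds both groups, 29 probes were higher and 94 lower.

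**Figure D4:**
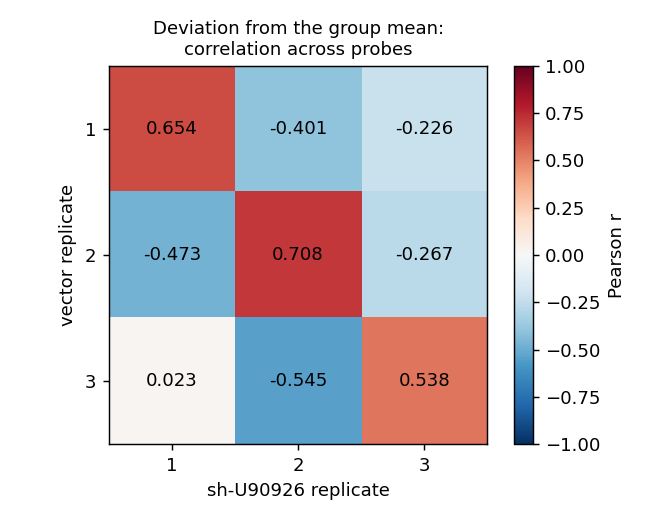
Each square gives the Pearson correlation, across tested probes, of the deviations from the group mean between a vector array (rows) and an sh-U90926 array (columns). Same-numbered arrays correlate at 0.654, 0.708 and 0.538, and the other squares lie at or below 0.023.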

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

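The scan run, GC content, random slide, pair-left-out and combined settings were chosen after the result was seen. Against 1370 rises and 1738 falls, rises numbered 708 after normexp, 609 with probes well above background on all arrays, 2619 with array weights and 2433 in the authors' table, which holds only probes with differences of at least 1 log2 unit. Of its probes tested here, 4774 of 4805 had an unadjusted limma p under 0.05 in the main fit, so its count is that of an already selected set. Both counts moved without a filter (241 rises, 513 falls), with probes well above background on any array (568 and 945), at adjusted p under 0.01 (317 and 621), at unadjusted p under 0.05 with a 2-fold change (3586 and 3106), with the slide as a block (29 and 94, only slide 2 holds both groups) and in scan run 2 alone (11 and 49, 2 arrays against 2). The replicate block gave 5547 and 4045, with GC trends removed 5332 and 4136, with the percentile over probes detected on all arrays 8952 and 3156, without pair 1 971 and 1421, without pair 2 4833 and 3640 and without pair 3 2356 and 2507. Leaving out each array in turn gave 461 to 2486 rises and 718 to 2145 falls. The cause of these moves was not tested, except that fewer arrays or other sets of probes entered some fits. Quantile normalization, trend with robust, the run and random slide blocks and GC removal stayed within 1.5 times for both counts. The 20 followed probes were picked for large changes in these same arrays, so a lack of reversals was largely given by the choice. Of 514 values of these probes under the alternatives, 482 kept direction and threshold and 0 reversed, which does not extend to the other calls. The threshold was lost by 32 (17 in run 2 alone, 13 under the slide block, A_55_P2016462 in both). Of the 482, 20 come from the authors' table, which holds only differences of at least 1 log2 unit. Normexp lowered steep falls from 539 to 261, and the replicate block changed no call among the 20 followed probes. Signal near background limits the rises most: 25 of 150 steep rises, against 320 of 539 steep falls, were well above background on all arrays. Not run were the mean of a gene's probes, and every alternative for U90926, Cxcl2 and the gene lists, since probes carry no gene names here; testing each probe as itself is the main setting.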

Other observations

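The tests of overall signal, scan run, shared slide, shared run and replicate 3 were chosen after the result was seen, and so was the limit of 8-fold that defines a steep fall; for carry-over, a first test of how widely the remaining shares spread was replaced because it gave 12.6 in replicate 3 against 15.6 and 18.6 in the other sh-U90926 arrays and so decided nothing, and the limits of the second were set after the shares had been looked at.

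Probes against opposite strands of the same stretch tended to move together. Across 957 tested pairs that are reverse complements over at least 30 bases, the log2 differences correlated at r = 0.65 (Spearman's rho 0.368), against 0.912 for overlapping probes of the same strand, and in 34 of the 40 pairs (85.0%) with at least 1 probe past the threshold both had the same sign. In 15 of these pairs, which reuse some of their 25 probes, both passed and changed in the same direction, 14 times downwards. Such pairs may report sense and antisense RNA of shared regions or double-stranded label, which were not told apart. Probes with the pentamer ATTTA, the core of AU-rich elements that shorten the life of many cytokine mRNAs, were slightly more frequent among the probes that changed (9.83% of the steep falls and 10.0% of the steep rises, against 7.43% of the unchanged probes), but not beyond what their composition gave. The hypothesis that they would be was tested against unchanged probes of the same identifier series and A+T content. Of the steep falls 9.55% were expected to hold ATTTA (odds ratio 1.03, permutation p = 0.82, adjusted p = 0.93), and of the steep rises 9.41% (odds ratio 1.07, permutation p = 0.89, adjusted p = 0.93). Of the 10 pentamers made of 2 A and 3 T, ATTTA ranked 4 and 5. Probes cover only 60 bases of a transcript, so elements elsewhere were not searched.

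The 539 steep falls in the sh-U90926 arrays were weighed first. A lower overall signal in these arrays was not seen in the share of probes well above background, which was higher in them by 4.22 percentage points on average. That difference lies within the spread between arrays of a group (45.5% to 67.1% in vector), so it decides nothing by itself. The 75th percentile of the signal before scaling was 147, 147 and 108 in vector replicates 1, 2 and 3. In sh-U90926 replicates 1, 2 and 3 it was 176, 177 and 117, higher in each same-numbered pair. A lower signal of whole arrays is therefore argued against as the source of falls of at least 8-fold. Each scan run holds the same number of arrays of both groups, so a difference between the runs alone cannot give a difference between the groups. Steep falls picked in a single run were also not confined to it. At least 99.5% of them were lower by 1 log2 unit or more in the other run, against at most 9.34% of all tested probes. Faulty or cross-hybridising probes stay open: 96.0% of 50 overlapping probes were lower by 1 log2 unit or more, but 43 are steep falls themselves, 5 of the other 7 were lower, and overlapping probes would share a cross-hybridising sequence. The effect of the sh-U90926 virus also stays open as a hypothesis, as do off-target effects of the hairpin and any difference between the virus preparations, which the design cannot separate from the knockdown.

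Same-numbered arrays of different groups deviated together. A shared slide or scan run as the whole cause is argued against by the arrays of slide 2, which share both. There vector replicate 2 correlated at 0.708 with sh-U90926 replicate 2 but at -0.267 with sh-U90926 replicate 3, where either cause alone would give like values. Centring within groups of 3 pushes such values down, and sh-U90926 replicate 1, which shares neither, stood at -0.473 with vector replicate 2. A partial contribution is therefore not excluded. The replicate 3 arrays correlated at 0.538 on different slides, which argues against the slide as the whole cause. For the scan run, -0.267 is also the higher of the 2 correlations between different-numbered arrays of run 2 and of different groups, with the same limit from centring. GC content is argued against by the lowest same-number correlation, which stayed at 0.537 with each array's GC trend removed. Cells or RNA prepared together for each number remain a possible explanation that was not tested. The lowest level of a probe well above background on an array also went with the number. It was -4.79, -3.40 and -3.20 in vector replicates 1, 2 and 3, and -4.77, -3.83 and -3.17 in sh-U90926 replicates 1, 2 and 3. Whether a shared range of signal contributed was not tested.

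Replicate 3 was the highest sh-U90926 array for 415 of the 539 steep falls (77.0%), with a median 1.20 log2 units above the mean of the other 2. The negative control spots were also highest there, at -5.94, -4.95 and -4.29 (log2 signal minus the 75th percentile) in sh-U90926 replicates 1, 2 and 3. Only 59.4% of the steep falls were well above background on all 6 arrays, so values near background enter this difference. Carry-over of vector RNA adds the same share of the vector signal to every probe, 2.28% for the median excess (95% bootstrap interval 1.57 to 3.04). Of 145 steep falls with signals over 5000 in vector replicate 3, 15 kept under 0.783%, 6 kept under 0.2% and the lowest kept 0.0417%. These 15 are 10.3%, with an exact 95% binomial interval from 5.91 to 16.5. That lies above the 2% allowed to carry-over but includes the 10% set to exclude it. The low shares argue against a constant share as the source of the whole excess. Against this, 119 of the 145 had a higher share in replicate 3 than the mean of the other 2 sh-U90926 arrays. A smaller carry-over was not excluded. The scaling of sh-U90926 replicate 3 stays open. Uncalled probes of the same level were already 0.70 log2 units higher there. The excess of the steep falls, 0.504, has a 95% bootstrap interval from 0.418 to 0.610 that includes the limit of 0.5 set for the test. The intervals for carry-over and scaling were taken over probes, which are not independent, so they measure only the scatter among probes. A shift shared with vector replicate 3 also stays open, since the difference there was 0.424 of that in sh-U90926 replicate 3, between the limits set. A weaker knockdown in this sample may contribute and was not tested, because the level of U90926 was not analysed here.

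The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 3108 probes, the value that 1 split reached, and the highest of the other splits gave 0. With the pairs as a block, 4 splits part all 3 pairs. The real split, again 1 of them, gave 9592 probes and the highest other 0. Every other split mixes vector and sh-U90926 arrays, so a large group difference widens the spread within its groups. The counts of 0 therefore say nothing of the cause of the difference.

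The E1A spike-in controls gave far lower signals in run 1 than in run 2. The median signal of the brightest of 4 E1A controls examined was 177 and 20.6 on the run 1 arrays (vector and sh-U90926 replicate 1) and 12489 to 19004 on the run 2 arrays. In the authors' deposited table, 4805 of 4806 probes were among those tested here, all 4805 with the same direction. The table comes from the same 6 arrays and holds only differences of at least 1 log2 unit, and 4774 of the 4805 had an unadjusted limma p under 0.05 here. The shared direction is therefore no independent evidence. Of the 4805 probes, 2991 passed the threshold without the pairs and 4675 with the pairs. A further 117 probes that passed without the pairs are absent from the table.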
